A study of Mus musculus with 18 samples.

How the data were processed

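RNA sequencing was carried out on hematopoietic progenitors from fetal livers of CD-1 mouse embryos, transduced with retroviral short hairpin RNAs (shRNAs) against Pcbp1 or Pcbp2 or with control shRNAs. The 18 libraries form 6 groups of 3: control, PCBP1 knockdown and PCBP2 knockdown, each at Day 0 (the end of the expansion culture) and Day 2 (after 2 further days in erythroid differentiation medium). Per the labels' protocols, libraries were made from total RNA with a TruSeq kit. The replicates of a knockdown are different hairpins (numbers 1, 3 and 4), and the replicates of the control are 2 scrambled hairpins (SCR-1, SCR-2) and 1 luciferase hairpin (LUC-1). The labels do not say whether the samples came from separate cultures or litters, so the p-values measure the spread between these samples.

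Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 1.46.0, aligned to GRCm38 with STAR 2.5.3a, handled with SAMtools 1.9 and quantified with Salmon 0.11.3. The authors deposited 1 Salmon table per library, with an estimated count (expected_counts) and an effective length in bases for each transcript. They also deposited 4 tables of local splicing variations, 1 for each knockdown and day. A local splicing variation is the set of junctions, and sometimes a retained intron, that leave or enter one exon. Per the file headers, these tables give for each junction the expected share of use (percent spliced in, PSI, as a fraction) in the pooled control and knockdown libraries, the expected change in PSI, and the posterior probability that the change is at least 0.20. The tool and the test behind these tables are not stated for these files, no depth or error is given, and they were read as the authors' values. Changes in PSI are given as knockdown minus control, in percentage points.

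Each Salmon table lists 111706 transcripts, of which 110403 matched the GENCODE M21 annotation of GRCm38. The 1303 others held between 0.275% and 0.579% of the estimated reads of a library and were not used. Counts were summed over transcripts to 46167 genes and rounded to whole numbers. The edgeR expression filter kept 17500 genes. Normalisation used TMM scaling factors, and a single model with 6 group means (12 residual degrees of freedom) was fitted to the 18 libraries with edgeR 4.0.16 (quasi-likelihood F tests, common dispersion 0.0169) in R 4.3.3. Log2 fold changes are the fitted values, with a standard error in parentheses, and n = 3 per group throughout. CPM are normalised read counts on the TMM-scaled library size, as mean ± SD. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes, and "rose", "fell" and "changed" are kept for called genes. The comparisons were each knockdown against control on each day, the knockdowns against each other on each day, Day 2 against Day 0 within each condition, and the change of each knockdown effect between the days. Because the spread between libraries differed by day (common dispersion 0.00766 in the 9 libraries of Day 0 and 0.0300 in the 9 of Day 2), each comparison within a day was also fitted on the 9 libraries of that day alone, an alternative chosen after seeing the data.

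The genes named follow a rule: Pcbp1 to Pcbp4 and Hnrnpk in every comparison; up to 8 called genes each way with the largest change, an average log2 CPM of at least 2 and groups that do not overlap (fewer than 4 passing were filled up to 4 by the smallest p, as values); up to 4 members of each list by smallest p; and all globins and reported PCBP mRNA targets. Some genes that this rule names are not reported here. The model, comparisons, thresholds, lists, naming rule and alternatives were chosen before the data were examined, except where a choice is said to have followed the data.

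Lists were tested with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation and with fry, adjusted over 30 lists. The lists were PCBP family and hnRNP K, globins, erythroid transcription factors, heme synthesis, iron handling, erythroid membrane and cytoskeleton, terminal erythroid maturation, progenitor and early hematopoietic genes, DNA replication, mitosis, p53 targets, CDK inhibitors, interferon response, integrated stress response, ribosomal proteins, cholesterol synthesis, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, immediate-early and heat-shock genes, splicing factors and hnRNPs, megakaryocyte, granulocyte, macrophage and monocyte, mast cell, basophil and eosinophil, hepatocyte, endothelial and stromal, lymphoid markers, reported PCBP mRNA targets, and erythroid splicing genes. Pcbp1 and Pcbp2 are in both the PCBP family and the erythroid splicing lists, so the hairpin targets are part of those results. Lists share other members, such as Mbnl1 (splicing factors and erythroid splicing), so their results are not independent. Counts "adjusted over the list alone" used the Benjamini-Hochberg method within a list. A splicing variation was called changed at a PSI change of at least 0.2 with a probability of at least 0.95. Transcript shares within a gene were computed from the estimated counts and tested with edgeR diffSpliceDGE (Simes method) over 8556 genes and 38216 transcripts.

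The gene test was tested on simulated data made from these counts with 200 changed genes among 17029. At Day 0, 3 false calls arose in each comparison with control (2.97% of the calls for PCBP1, 2.5% for PCBP2), and 11 (7.64%) and 10 (6.49%) in the 9-library fits. At Day 2, 51 (33.8%) and 37 (27.4%) arose with the pooled spread and 9 (9.47%) and 4 (4.76%) in the 9-library fits, so genes that passed both fits are given first for Day 2. Of the genes changed by 1 log2 unit, 40 of 66 were called for PCBP1 at Day 0 and 40 of 65 at Day 2, and of those changed by 0.5 log2 units 7 of 67 and 4 of 63. In the 9-library fits these were 41 of 58 and 33 of 58, and for 0.5 log2 units 39 of 61 and 0 of 55. The transcript share test called 69 false genes among 89, so its calls are given only as counts. Alternatives tried were DESeq2 1.42.0, limma-voom, scaling to library totals, other expression filters, a 2-fold minimum, offsets for effective length, only the compared libraries, replicate blocks, leaving out each library and, chosen after seeing the data, scrambled controls only, removal of the GC trend in each library (lowess, span 0.3) and the 9 libraries of a day. Tables were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, annotation with rtracklayer 1.62.0, and figures drawn with matplotlib 3.10.9.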

Results

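RNA was sequenced from mouse fetal liver progenitors cultured after transduction with shRNAs. PCBP1 and PCBP2 are poly(C)-binding proteins, RNA-binding proteins that act in splicing, translation and mRNA stability and that also carry iron. The 18 libraries covered 3 conditions at Day 0 and Day 2, with 3 libraries in each of the 6 groups. The estimated reads per library were 31109684, 36564306 and 32184829 in the Day 0 controls (SCR-1, SCR-2 and LUC-1), 30635061, 31573031 and 33106385 in the Day 0 PCBP1 knockdown (hairpins 1, 3 and 4) and 34024802, 54096339 and 32040290 in the Day 0 PCBP2 knockdown. At Day 2 they were 34692385, 38006881 and 34331121 in the controls, 28233193, 28698919 and 29535905 in the PCBP1 knockdown and 27033440, 29872250 and 29050247 in the PCBP2 knockdown. At these depths 17500 genes were tested.

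The first principal component of all libraries separated the days and held 88.6% of the variance. Among the 9 libraries of Day 2, the LUC-1 control lay apart from both scrambled controls on the first component (-74.9 against -1.27 and -11.4). At Day 0 it did so on the second (-26.7 against 17.0 and 8.63). Globin transcripts took between 0.30% and 0.48% of the estimated reads at Day 0. At Day 2 they took 27.59%, 31.67% and 33.46% in the controls, 24.73%, 25.67% and 26.58% in the PCBP1 knockdown and 28.59%, 25.89% and 27.6% in the PCBP2 knockdown.

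The first question was how far each hairpin lowered its target. Pcbp1 (ENSMUSG00000051695, GRCm38 chromosome 6, 86524492 to 86526321, minus strand) was measured at 186, 197 and 206 CPM in the Day 0 controls SCR-1, SCR-2 and LUC-1. PCBP1 hairpins 1, 3 and 4 left 14.2, 59.4 and 24.3 CPM, which were 7.21%, 30.3% and 12.4% of the control mean. At Day 2 the controls had 241, 281 and 284 CPM of Pcbp1 and the PCBP1 hairpins 15.6, 57.2 and 40.4 CPM. Pcbp2 (ENSMUSG00000056851, chromosome 15, 102470539 to 102500061, plus strand) was measured at 282, 285 and 299 CPM in the Day 0 controls and at 71.0, 70.3 and 73.5 CPM with PCBP2 hairpins 1, 3 and 4. At Day 2 the Pcbp2 values were 229, 225 and 247 CPM in the controls and 39.5, 37.0 and 48.0 CPM with the PCBP2 hairpins. Pcbp1 fell in the PCBP1 knockdown by 2.59 log2 units (0.47) at Day 0 (edgeR quasi-likelihood adjusted p = 0.0231) and by 2.83 (0.49) at Day 2 (adjusted p = 0.00239). Pcbp2 fell in the PCBP2 knockdown by 2.01 (0.10) at Day 0 (edgeR adjusted p = 3.05e-12) and by 2.49 (0.10) at Day 2 (adjusted p = 5.71e-14). Leaving out single libraries gave Day 0 Pcbp1 values of -3.35 to -2.22, and the call was lost without hairpin 1, hairpin 4 or any 1 of the controls, and with the GC trend removed (-2.34).

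The untargeted paralog was not called in either knockdown. Pcbp2 was at 273, 285 and 293 CPM in the Day 0 PCBP1 knockdown and at 181, 215 and 193 CPM at Day 2, a log2 value of -0.25 with an edgeR adjusted p of 0.0828. With the GC trend removed, Pcbp2 was called in the Day 2 PCBP1 knockdown (-0.38, adjusted p = 0.016 by edgeR). Pcbp1 was at 193, 179 and 212 CPM in the Day 0 PCBP2 knockdown and at 240, 214 and 250 CPM at Day 2 (log2 -0.01 and -0.19). Hnrnpk, which codes for the related poly(C)-binding protein hnRNP K, had log2 values at Day 0 and Day 2 of 0.02 and -0.11 in the PCBP1 knockdown and 0.08 and 0.10 in the PCBP2 knockdown. Pcbp3 and Pcbp4 were not called in any knockdown comparison with control.

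**Figure D1:**
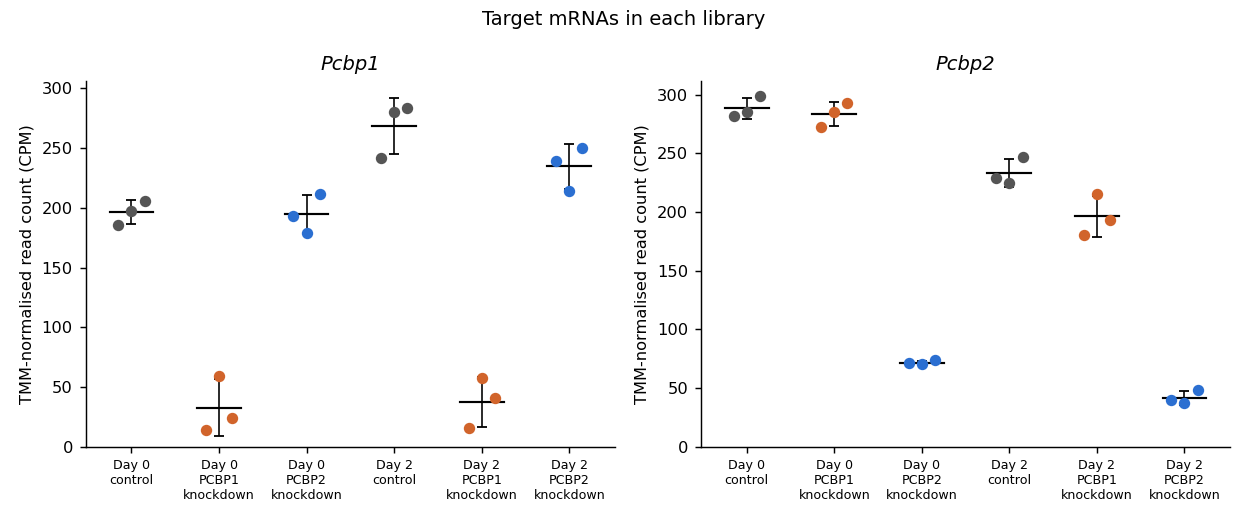
CPM of Pcbp1 and Pcbp2 in each library, by condition and day, with points for the 3 libraries of a group and bars for their mean and SD. Pcbp1 lay between 14.2 and 59.4 CPM with the PCBP1 hairpins and between 186 and 284 CPM in the controls.

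The next comparison asked which transcripts differed after PCBP1 knockdown in expanding progenitors, before differentiation. At Day 0, 6 genes rose and 150 fell (edgeR quasi-likelihood test), and 1795 genes had an unadjusted p under 0.05. Got1, the cytosolic aspartate aminotransferase, fell by 1.33 log2 units (0.15, edgeR adjusted p = 3.75e-05). Galk1, which codes for galactokinase, fell by 1.44 (0.19, adjusted p = 2.23e-04 by edgeR). Ccdc22, which codes for a subunit of an endosomal sorting complex, fell by 1.24 (0.16). Fdxr codes for the mitochondrial ferredoxin reductase, which feeds electrons to iron-sulfur cluster and heme synthesis, and it fell by 1.30 (0.16, edgeR adjusted p = 2.07e-04). Blvrb, the biliverdin reductase abundant in red cells, was at 63.7 ± 11 CPM against 133 ± 11 CPM in the controls and fell by 1.06 (0.14). Col11a2, a collagen chain gene, fell by 1.31 (0.18). Each of these 6 genes stayed called in every alternative fit. The gene for the red cell pyruvate kinase, Pklr, fell by 0.82 (0.14, edgeR adjusted p = 0.00524). The heme synthesis enzyme gene Alad fell by 0.71 (0.15), the serine hydroxymethyltransferase gene Shmt2 by 0.62 (0.10) and the mevalonate kinase gene Mvk by 0.71 (0.16). Zfpm1, which codes for the GATA1 partner FOG1, fell by 0.51. The apolipoprotein gene Apoa1 fell by 1.06 (0.26, edgeR adjusted p = 0.0495), and the scaffold gene Iqgap2 rose by 0.46 (0.10, adjusted p = 0.0184). Hba-a2, an alpha-globin gene whose reads cannot be separated surely from its near-identical copy Hba-a1, had a log2 value of 0.88 (0.19, edgeR adjusted p = 0.0286).

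The genes that fell in the Day 0 PCBP1 knockdown were rich in G and C. Their median GC content was 57.8%, against 47.0% for the genes that rose and 49.2% for the others. Across genes, which are not independent replicates, the log2 fold change and GC content had a Spearman rho of -0.399. With the GC trend of each library removed, 18 of the 150 genes were still called lower, and Alad, Shmt2, Mvk, Zfpm1, Apoa1 and Pcbp1 were not. Iqgap2 was no longer called higher. The median of the 150 genes moved from -0.67 (quartiles -0.88 and -0.57) to -0.47 (quartiles -0.62 and -0.36). The 9 libraries of Day 0 alone, with their smaller spread, gave 248 genes that rose and 863 that fell, and 130 and 203 with the GC trend removed, 191 of the 863 among them. Leaving out single libraries gave 139 genes without LUC-1, 38 without SCR-1, 28 without SCR-2 and 19, 92 and 45 without hairpins 1, 3 and 4.

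**Figure D2:**
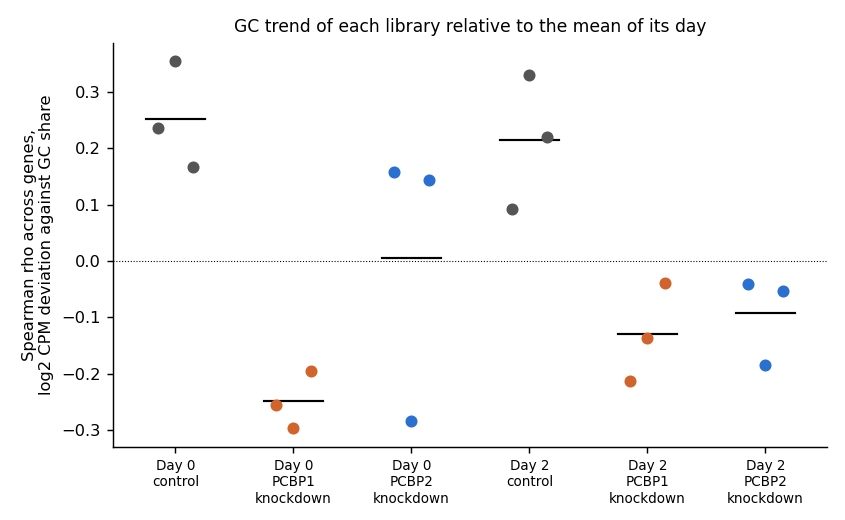
Spearman's rho across genes between GC content and the deviation of log2 CPM from the mean of the day, for each of the 18 libraries, with a line at the mean of a group. The controls lie between 0.0918 and 0.355 and the PCBP1 knockdown libraries between -0.297 and -0.0392.

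Among the gene lists at Day 0, camera called 6 of 30 in the PCBP1 knockdown, and an estimated correlation left none of them. The ribosomal proteins had a median of -0.13, and 2 of 78 fell, 6 when adjusted over the list alone (camera adjusted p = 1.18e-04, adjusted p = 0.947 with an estimated correlation). Heme synthesis had a median of -0.15, with 1 of 15 genes lower, 3 adjusted over the list alone (camera adjusted p = 0.00353, adjusted p = 0.687 with an estimated correlation). The erythroid transcription factors had a median of -0.18 (camera adjusted p = 0.00823, then 0.687 with an estimated correlation). The integrated stress response genes had a median of -0.09 (camera adjusted p = 0.00823, then 0.793). The macrophage and monocyte genes had a median of -0.30 with no gene called (camera adjusted p = 0.0194, then 0.687). The PCBP family and hnRNP K had a median of -0.24 (camera adjusted p = 0.0245, then 0.423). With the GC trend removed, the erythroid transcription factors (camera adjusted p = 0.873) and the integrated stress response (0.448) were no longer called.

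The same question for PCBP2 knockdown at Day 0 gave 4 genes that fell and none that rose by the edgeR quasi-likelihood test, where DESeq2 called 13 and 563 genes had an unadjusted p under 0.05. Without single libraries 2 to 5 genes were called, and the calls of Cdc25b and Depdc1b were lost without SCR-1, SCR-2, hairpin 1 or hairpin 3. Besides Pcbp2, Btbd2, which codes for a BTB-domain protein, fell by 1.51 (0.17, edgeR adjusted p = 5.32e-05). Cdc25b, the phosphatase that activates cyclin-dependent kinases at mitotic entry, fell by 0.75 (0.12, edgeR adjusted p = 0.0106). Depdc1b, a gene of the G2/M transition, fell by 0.75 (0.13, adjusted p = 0.0197 by edgeR). Higher values that did not pass include 1.28 (0.31) for the synapsin gene Syn3, 0.40 for Fam45a, 0.43 for the topoisomerase gene Top3a and 0.32 for the histone H3.3 gene H3f3b. Camera called 8 lists at Day 0. Outside the PCBP family (camera adjusted p = 3.68e-20, then 1.4e-05 with an estimated correlation), no member of them was called. The macrophage and monocyte genes had a median of -0.26 (camera adjusted p = 9.51e-07, then 0.133) and cholesterol synthesis -0.12 (1.63e-06, then 0.219). Ribosomal proteins (-0.04), mitosis (0.07), splicing factors (0.05), megakaryocyte (-0.07) and granulocyte genes (-0.11) had camera adjusted p values of 0.00914 to 0.0405, and adjusted p = 0.987 with an estimated correlation.

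Compared directly at Day 0, which asks where the knockdowns differ, 42 genes were higher and 3 lower in the PCBP2 knockdown than in the PCBP1 knockdown (edgeR). Without single libraries 10 to 38 genes were called, against 45. Got1 was higher by 1.34 (0.15, edgeR adjusted p = 3.02e-05), and Ccdc22 and Col11a2 both by 1.19, Fdxr by 1.11 and Galk1 by 1.13. Depdc1b was lower (-0.72, 0.13, edgeR adjusted p = 0.0084). Blvrb (0.70), Pklr (0.69), Alad (0.69), Apoa1 (1.22) and the filament gene Gfap (1.15) were also higher, and they were not called with the GC trend removed. Pcbp1 differed by 2.58 without passing (edgeR adjusted p = 0.0513). Camera called 7 lists. The PCBP family and hnRNP K list tested lower although its median was 0.05 (camera adjusted p = 4.45e-05, then 0.0108 with an estimated correlation). Heme synthesis (camera adjusted p = 1.45e-04, then 0.622) and the erythroid transcription factors (0.00337, then 0.538) tested higher in the PCBP2 knockdown. The integrated stress response (camera adjusted p = 8.55e-04), the erythroid membrane (0.00401), cholesterol synthesis (0.023, lower) and ribosomal proteins (0.0368) had adjusted p = 0.893 to 0.935 with an estimated correlation.

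After 2 days of differentiation, the comparison asked how PCBP1 knockdown altered the erythroid program. At Day 2, 953 genes rose and 1315 fell in the PCBP1 knockdown (edgeR quasi-likelihood test). The 9 libraries of Day 2 alone gave 291 that rose and 641 that fell, and 917 genes were called by both fits. All genes in this paragraph passed both. Of the 90 named genes called with the pooled spread, 37 kept their call in every alternative fit. Several erythroid regulators fell. Klf1, the erythroid Krüppel-like factor, was at 188 ± 2.7 CPM against 369 ± 93 CPM and fell by 0.97 (0.14, edgeR adjusted p = 7.45e-05). Gfi1b, a repressor needed for erythroid and megakaryocyte development, fell by 0.70 (0.10), Nfe2, a globin enhancer-binding factor, by 0.68 (0.12) and the cell-cycle regulator gene E2f2 by 0.63 (0.10). Several red cell membrane genes fell, among them Dmtn, which codes for the actin-bundling protein dematin (-0.87, 0.12, edgeR adjusted p = 6.69e-05), the Rh antigen gene Rhd (-0.68, 0.13) and the adhesion molecule gene Icam4 (-0.85, 0.16). The glucose transporter gene Slc2a1 fell by 1.24 (0.14, edgeR adjusted p = 9.23e-06). In heme synthesis and mitochondrial transport, Ppox (protoporphyrinogen oxidase) fell by 1.08 (0.15), Abcb10 by 0.66 (0.10), Slc25a38, the glycine carrier, by 0.50 (0.10) and Abcb6, a porphyrin transporter, by 0.44 (0.09). Blvrb fell by 1.11 (0.14, edgeR adjusted p = 1.94e-05), as at Day 0, and the red cell peroxiredoxin gene Prdx2 by 0.50 (0.09).

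A further group consisted of amino acid and stress-response genes. Atf5, a stress-induced transcription factor gene, fell by 1.29 (0.16, edgeR adjusted p = 4.11e-05). The amino acid transporter gene Slc7a5 fell by 0.67 (0.09), Shmt2 by 0.89 (0.11) and the alanyl-tRNA synthetase gene Aars by 0.57 (0.08). Immediate-early genes fell too: Ier2 by 1.22 (0.18), the phosphatase gene Dusp1 by 1.07 (0.16) and the AP-1 subunit gene Junb by 1.32 (0.27, edgeR adjusted p = 0.00583). Cebpb, a myeloid and stress-induced transcription factor gene, fell by 1.74 (0.23), the metallothionein gene Mt1 by 1.92 (0.32), the p53 target Bbc3 by 1.08 (0.22) and the exonuclease gene Isg20 by 0.85 (0.12). Among the genes that rose most were Reps2, an endocytic adaptor gene (2.03, 0.20, edgeR adjusted p = 1.74e-06), Trdc, the T-cell receptor delta constant gene (2.56, 0.24), and Mtrf1, a mitochondrial release factor gene (1.92, 0.24). The retinaldehyde dehydrogenase gene Aldh1a1 rose by 1.98 (0.24), the interleukin-7 receptor gene Il7r by 1.86 (0.32) and the transporter gene Abca8b by 1.78 (0.23). The splicing regulators Mbnl1 and Mbnl3 rose by 0.55 and 0.64, and the megakaryocyte tubulin gene Tubb1 rose by 0.55.

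Among the globins, Hbb-bs fell by 0.40 (0.12, edgeR adjusted p = 0.0292) in the Day 2 PCBP1 knockdown. Hba-a1 had a value of -0.79 (0.22, edgeR adjusted p = 0.0297), with reads shared with Hba-a2, and the other 6 globins tested were not called. Hist1h2al, a histone gene with near-identical copies, had a value of -3.33 (0.46). Genes that rose only with the pooled spread included the replication genes Rfc3 (0.61), Gins3 (0.59) and Mcm4 (0.47) and the mitosis genes Top2a (0.54), Ttk (0.49), Cdk1 (0.44) and Ccnb1 (0.41). Without the LUC-1 control of Day 2, the members called higher went from 4 to 1 in the DNA replication list and from 8 to 0 in the mitosis list. Scaled to library totals, the median of all genes moved by 0.23 and the calls became 3459 higher and 628 lower. Without LUC-1, PCBP1 hairpin 1 or hairpin 4 the calls were 1498, 1489 and 1532, against 2268. With the GC trend removed, 874 of the 1315 genes that fell were still called lower, and 312 of the 641 in the 9-library fit.

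Camera called 11 lists in the Day 2 PCBP1 knockdown, all 11 again in the 9-library fit, and none with an estimated correlation. The integrated stress response list had a median of -0.46, and 14 of 24 genes fell, 16 when adjusted over the list alone (camera adjusted p = 1.83e-11, adjusted p = 0.203 with an estimated correlation). Of the erythroid membrane and cytoskeleton genes, 15 of 23 fell, 17 adjusted over the list alone, at a median of -0.37 (camera adjusted p = 1.56e-09, adjusted p = 0.203 with an estimated correlation). Of the erythroid transcription factors, 2 rose and 9 of 19 fell, 2 and 11 adjusted over the list alone, with a median of -0.33 (camera adjusted p = 1.2e-05, adjusted p = 0.107 with an estimated correlation). In heme synthesis 1 rose and 8 of 15 fell, 1 and 10 adjusted over the list alone, median -0.32 (camera adjusted p = 1.45e-05, adjusted p = 0.289 with an estimated correlation). The erythroid splicing genes had 3 that rose and 13 of 29 that fell, 3 and 17 adjusted over the list alone, median -0.33 (camera adjusted p = 2.28e-05, adjusted p = 0.107 with an estimated correlation). Pcbp1, the target of the hairpins, is a member of this list. Terminal erythroid maturation had 1 that rose and 8 of 24 that fell, 1 and 9 adjusted over the list alone, median -0.26 (camera adjusted p = 1.81e-04, adjusted p = 0.49 with an estimated correlation). In the immediate-early and heat-shock list 7 of 16 fell, 1 higher and 7 lower adjusted over the list alone, median -0.38 (camera adjusted p = 0.00383, adjusted p = 0.341 with an estimated correlation). DNA replication (median 0.27, 4 of 28 rose, camera adjusted p = 1.23e-04), mitosis (0.20, 8 of 26 rose, 1.81e-04), nuclear-encoded oxidative phosphorylation (0.18, 5 of 34 rose and 1 fell, 0.00186) and mitochondrially encoded transcripts (0.28, 0 of 13 called, 0.0238) tested higher, with adjusted p = 0.649 with an estimated correlation. Adjusted over the list alone, 7 replication and 10 mitosis genes were higher.

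The other 19 lists were not called by camera in the Day 2 PCBP1 knockdown. The globins had 2 of 8 lower, a median of -0.04 and a mean of 0.06. Iron handling had 1 higher and 3 lower of 17, the p53 targets 4 higher and 1 lower of 24, and the interferon response 6 higher and 1 lower of 26 (camera adjusted p = 0.0701). Ribosomal proteins had 1 higher and 2 lower of 78, cholesterol synthesis 3 lower of 22, glycolysis 3 lower of 17, and splicing factors and hnRNPs 4 higher and 3 lower of 43. Progenitor and early hematopoietic genes had 1 higher of 20, and the CDK inhibitors 0 of 6. Of the lists for other lineages, megakaryocyte had 2 higher and 3 lower of 18, granulocyte 1 lower of 20, macrophage and monocyte 1 lower of 17, and mast cell, basophil and eosinophil 1 higher of 11. The hepatocyte list had 0 of 8 called, endothelial and stromal 1 higher and 1 lower of 8, and lymphoid markers 1 higher of 5. The reported PCBP mRNA targets had 1 lower of 5, and the PCBP family and hnRNP K 1 lower of 5. Adjusted over the list alone, the globins had 1 higher and 3 lower, the p53 targets 6 higher and 2 lower, and glycolysis 3 higher and 3 lower.

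**Figure D3:**
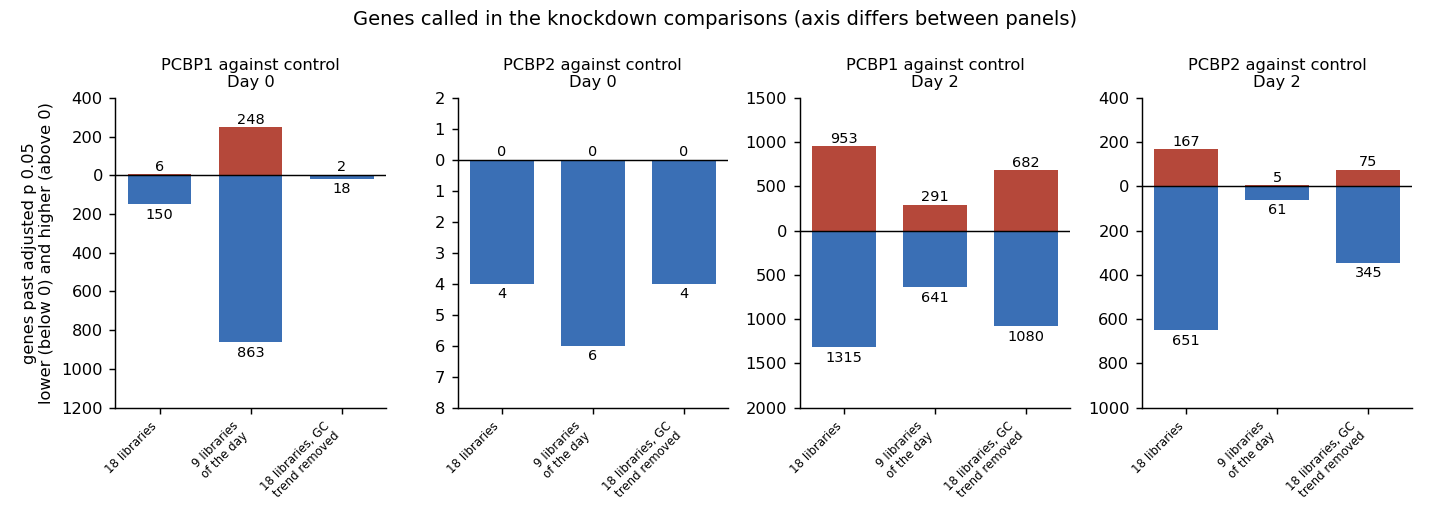
Number of genes that rose or fell in each knockdown comparison by the edgeR quasi-likelihood test on all 18 libraries, on the 9 libraries of the same day, and on all 18 with the GC trend removed, on axes that differ between panels. In the Day 2 PCBP1 knockdown the count went from 2268 to 932, and at Day 0 from 156 to 1111.

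For PCBP2 knockdown at Day 2, the same question gave 167 genes that rose and 651 that fell (edgeR quasi-likelihood test). The 9 libraries of Day 2 alone gave 5 that rose and 61 that fell, and 64 genes were called by both fits. Scaled to library totals, the median of all genes moved by 0.20 and the calls became 974 higher and 219 lower. Of the 61 named genes called with the pooled spread, 1 kept its call in every alternative fit. Those called by both fits included several transcription factor genes. Zfpm1 fell by 0.90 (0.13, edgeR adjusted p = 3.89e-04; -0.35 with the GC trend removed), Klf1 by 0.86 (0.14, adjusted p = 0.00125 by edgeR), Zbtb7a, a repressor of fetal globin genes, by 0.76 (0.13), and Srebf2, the regulator of cholesterol synthesis, by 0.83 (0.12). Trim58, a ubiquitin ligase gene of late erythroblasts, fell by 0.80 (0.11, edgeR adjusted p = 3.81e-04). Blvrb fell by 0.87 (0.14, edgeR adjusted p = 0.00112), Junb by 1.29 (0.27), the lens galectin-related gene Grifin by 1.26 (0.21) and the respiratory chain gene Uqcrq by 0.86. Pcdh7, a protocadherin gene, rose by 1.08 (0.20, edgeR adjusted p = 0.00353). Rpl13a (-0.67) and Rplp1 (-0.88, 0.19) were called, with reads that pseudogenes can share.

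With the pooled spread alone, the erythroid regulators Gata1 (-0.44, 0.09), Gfi1b (-0.51, 0.10) and Runx1 (-0.49, 0.13, edgeR adjusted p = 0.0347) also fell in the Day 2 PCBP2 knockdown. So did Dmtn (-0.64, 0.12), Rhd (-0.63), the adducin gene Add1 (-0.48), Slc2a1 (-0.66, 0.14), the hexokinase gene Hk1 (-0.48) and the heme genes Urod (-0.43), Alad (-0.52) and Abcb10 (-0.43). The ubiquitin ligase gene Siah2 rose by 1.01 (0.20), Mtrf1 by 1.31 (0.26), the autophagy gene Atg9b by 1.27 (0.23) and the death receptor gene Fas by 0.78. Hba-a2 had a value of 0.89 (0.18, edgeR adjusted p = 0.0101), with reads shared with Hba-a1, and no other globin was called. Of the genes that fell, 274 of 651 were still called lower with the GC trend removed, and their median GC content was 56.8% against 49.0% for the genes not called. The median of the 651 moved from -0.59 to -0.47. In the 9-library fit, 5 of the 61 genes that fell stayed called with the trend removed, and the median of the 61 moved from -0.86 to -0.61. Without PCBP2 hairpin 4 the calls were 448, against 818, and with the 6 compared libraries alone they were 8.

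Camera called 10 lists in the Day 2 PCBP2 knockdown, and again all 10 in the 9-library fit. The erythroid transcription factors had a median of -0.39, and 7 of 19 fell, 13 when adjusted over the list alone (camera adjusted p = 2.81e-11, adjusted p = 0.00423 with an estimated correlation). Of the erythroid splicing genes 8 of 29 fell, 13 adjusted over the list alone, median -0.19 (camera adjusted p = 1.68e-10, adjusted p = 0.00336 with an estimated correlation). Pcbp2, the target of the hairpins, is in this list, which shares members with other lists. The PCBP family, which also holds Pcbp2, had a median of -0.19 (camera adjusted p = 1.61e-07, adjusted p = 0.00291 with an estimated correlation). The lowered target is therefore part of the results of both lists, for which no value without it is given. Of the erythroid membrane genes 8 of 23 fell, 14 adjusted over the list alone, median -0.31 (camera adjusted p = 7.08e-09, adjusted p = 0.252 with an estimated correlation). Terminal maturation (5 of 24 fell, median -0.21, camera adjusted p = 4.6e-06) and heme synthesis (4 of 15 fell, median -0.27, camera adjusted p = 5.68e-05) had adjusted p = 0.322 with an estimated correlation, and 8 genes lower in each when adjusted over the list alone. The p53 targets tested higher, with 2 that rose and 1 of 24 that fell, 9 and 1 adjusted over the list alone, median 0.24 (camera adjusted p = 6.05e-04, adjusted p = 0.704 with an estimated correlation). Mitosis tested lower with 1 of 26 called, median -0.18 (camera adjusted p = 0.00183, adjusted p = 0.739 with an estimated correlation). Glycolysis (2 of 17 fell, median -0.23, camera adjusted p = 0.0147, adjusted p = 0.64 with an estimated correlation) and ribosomal proteins (6 of 78 fell, median -0.06, camera adjusted p = 0.0332, adjusted p = 0.889 with an estimated correlation) were not called with the GC trend removed. Of the lists not called, the integrated stress response had 3 lower of 24, the macrophage genes a median of 0.17 and a mean of -0.23, and the progenitor genes a median of 0.14 and a mean of -0.07.

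**Figure D4:**
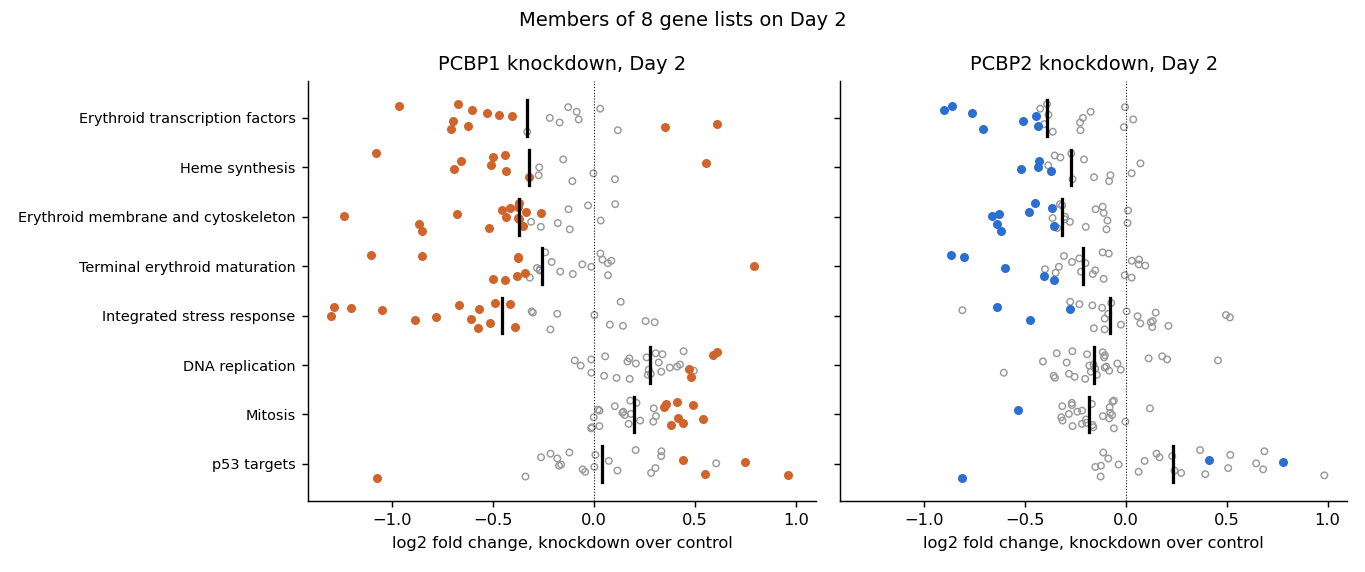
Log2 fold change of each tested member of 8 gene lists at Day 2, for PCBP1 and PCBP2 knockdown against control, with filled points for called genes, open points for the others and a black line at the median. The erythroid transcription factors had medians of -0.33 and -0.39, and the integrated stress response -0.46 in the PCBP1 knockdown.

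The direct comparison at Day 2 asked which changes were particular to one knockdown. Relative to the PCBP1 knockdown, 846 genes were higher and 1312 lower in the PCBP2 knockdown (edgeR), 273 and 246 in the 9-library fit, and 1052 genes were called without PCBP1 hairpin 1 and 1093 without PCBP2 hairpin 4. The genes that follow passed both fits. Among stress-response genes, Atf3 was higher by 1.30 (0.18, edgeR adjusted p = 2.49e-04), Chac1, which degrades glutathione, by 1.36 (0.25), Slc7a5 by 0.50 (0.09), the asparaginyl-tRNA synthetase gene Nars by 0.59 (0.10), the co-chaperone gene Dnajb1 by 0.73 (0.11) and Dusp1 by 0.96 (0.16). Ppox was higher by 0.81 (0.15, edgeR adjusted p = 0.00187), and the transporter gene Slc35f5 by 1.56 (0.19). Pcbp1 was higher by 2.64 (0.48, edgeR adjusted p = 0.00486) and Pcbp2 lower (-2.24). Reps2 (-1.94, 0.20, edgeR adjusted p = 4.91e-06), Aldh1a1 (-1.98, 0.24), Trdc (-1.67, 0.23) and Il7r (-1.99, 0.32) were lower. So were the cytokine signalling gene Stat5b (-1.01, 0.17), the glycolysis gene Eno1 (-0.95, 0.16) and the division genes Top2a (-0.74, 0.14), Ttk (-0.75, 0.15), Ccne1 (-0.73, 0.15) and Rfc3 (-0.72, 0.15). The histone genes Hist1h2ac (1.36, 0.18) and Hist1h2bg (1.41) were called higher, with reads that near-identical copies can share.

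Camera called 8 lists between the knockdowns at Day 2, and none with an estimated correlation. Mitosis had 14 of 26 lower in the PCBP2 knockdown, 21 adjusted over the list alone, median -0.42 (camera adjusted p = 2.48e-11, adjusted p = 0.366 with an estimated correlation). DNA replication had 17 of 28 lower, 1 higher and 23 lower adjusted over the list alone, median -0.51 (camera adjusted p = 7.9e-09, adjusted p = 0.478 with an estimated correlation). The integrated stress response had 13 of 24 higher, 14 higher and 1 lower adjusted over the list alone, median 0.41 (camera adjusted p = 3.38e-09, adjusted p = 0.366 with an estimated correlation). Oxidative phosphorylation had 12 of 34 lower, 1 higher and 18 lower adjusted over the list alone, median -0.23 (camera adjusted p = 6.54e-07, adjusted p = 0.366 with an estimated correlation), and the immediate-early genes 2 of 16 higher, median 0.40 (camera adjusted p = 0.00326, adjusted p = 0.366 with an estimated correlation). Mitochondrially encoded transcripts had 1 of 13 lower, median -0.36 (camera adjusted p = 0.00361, then 0.79 with an estimated correlation). The PCBP family (camera adjusted p = 0.00564, then 0.199) and ribosomal proteins (0.0279, then 0.823) were lost in the 9-library fit, at 0.0752 and 0.0567.

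The overlap of the knockdowns addressed how much of the response they share. At Day 2, 52 genes were higher and 329 lower in both knockdowns, where lists drawn independently would share 9.09 and 48.9. Both comparisons use the same controls, which cannot be split between them. Counts simulated without any knockdown effect, with the same shared controls, gave a correlation of the log2 fold changes across genes of 0.489 (0.465 to 0.523) at Day 2 against 0.523 observed, and 0.507 (0.469 to 0.544) at Day 0 against 0.513 observed. By Spearman's rho the value was above the simulated range at Day 0 (0.489 against 0.448, 0.436 to 0.457) and below it at Day 2 (0.424 against 0.450, 0.430 to 0.465). The share of genes with the same sign was also above the range at Day 0 (69.5% against 66.9%) and below it at Day 2 (63.6% against 66.7%). With the GC trend removed, both were below the range on both days (rho 0.408 and 0.355, shares 65.5% and 61.0%). The covariance was 0.245 against 0.139 simulated at Day 2, a difference of 0.106, and 0.113 against 0.0749 at Day 0, a difference of 0.0378. Over genes with an average log2 CPM of at least 2 it was 0.0590 at Day 2 and 0.0196 at Day 0, with no simulated value for these genes. Simulated counts gave 0.5 genes called in both knockdowns at Day 2 against 381 observed, 146 with the GC trend removed, and part of the excess over independent lists may come from the shared controls. Counts without an effect leave few genes to call, so the 0.5 does not measure how far the responses are shared. Genes were simulated independently, without a GC trend or a library that stands apart, so such differences are not allowed for. At Day 0, Btbd2 was the 1 gene called in both. Between the days, 82 genes fell in the PCBP1 knockdown on both days, Blvrb among them, where 11.3 would be shared by independent lists. No gene was called in all 4 comparisons with control.

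Day 2 against Day 0 within each condition asked what differentiation itself changed. In the controls 7077 genes rose and 7413 fell (edgeR quasi-likelihood test). The receptor gene Kit, a progenitor marker, went from 381 ± 6.5 to 3.61 ± 0.57 CPM (-6.72, 0.14, edgeR adjusted p = 2.76e-22). Alas2, the erythroid first enzyme of heme synthesis, rose by 7.54 (0.15, edgeR adjusted p = 1.89e-22), and the band 3 gene Slc4a1 by 6.41. The adult beta-globin genes Hbb-bt and Hbb-bs rose by 7.83 (0.16) and 7.52 (0.16). The red cell enzyme gene Bpgm rose by 6.87, the reticulocyte ubiquitin ligase gene Ube2o by 6.73, the heme oxygenase gene Hmox1 by 7.86 and the ferritin gene Ftl1 by 5.14. The CDK inhibitor genes Cdkn1a and Cdkn1b rose by 6.40 and 5.22, the antiproliferative gene Btg2 by 7.01, Nfe2 by 4.67, Klf3 by 3.90, Foxo3 by 4.09 and Runx1 by 2.87. The progenitor regulators Myb (-4.56) and Myc (-2.63), the neutrophil granule genes Ctsg (-6.23) and Elane (-5.97), the glycolysis gene Hk2 (-4.62), the cholesterol synthesis genes Hmgcs1 (-4.02) and Lss (-4.42) and the splicing regulator Ptbp1 (-2.18) fell. Pcbp2 fell by 0.30 (0.09, edgeR adjusted p = 0.00497), Hnrnpk by 0.18 (adjusted p = 0.0309 by edgeR; 0.076 higher with genes of at least 1 CPM in 3 libraries), Pcbp3 by 3.33 and Pcbp4 by 4.76, and Pcbp1 was not called (0.45, 0.45, adjusted p = 0.359). These values are relative to a scale set by the day: with library totals the median of all genes moved by -1.63 in the controls, and Pcbp1 had a value of -1.19.

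Camera called 19 lists between the days in the controls, of which terminal erythroid maturation and the reported PCBP targets held with an estimated correlation. Terminal maturation had 23 of 24 genes higher (median 4.38, camera adjusted p = 7.84e-27, then 0.0118 with an estimated correlation). The reported PCBP targets had 4 of 5 (median 6.40, camera adjusted p = 4.73e-04, then 0.0448). These targets are Hba-a1, Hba-a2, Cdkn1a, Alox15 and Col1a1, so the list shares members with the globins and the CDK inhibitors. All 8 globins rose (median 7.57, camera adjusted p = 5.87e-07, adjusted p = 0.0668 with an estimated correlation), as did 20 of 23 membrane genes, 13 of 15 heme synthesis genes and 22 of 24 p53 targets. Cholesterol synthesis had 20 of 22 lower (median -2.86), DNA replication 26 of 28 (-1.77), mitosis 22 of 26 (-0.75), glycolysis 14 of 17 (-2.51), oxidative phosphorylation 28 of 34 (-1.09) and the progenitor genes 15 of 20 (-1.19). The granulocyte list had a median of 0.55 and a mean of -0.06, and the endothelial and stromal list a median of 1.17 and a mean of -0.30.

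In the PCBP1 knockdown 7053 genes rose and 7290 fell between the days, and 6570 of the higher and 6899 of the lower genes were those of the controls. In the PCBP2 knockdown 7149 rose and 7374 fell, of which 6666 and 6984 were those of the controls. Kit fell by 6.87 and 6.77, Alas2 rose by 7.63 and 7.73, Slc4a1 by 6.18 and 6.12 and Hbb-bs by 7.47 and 7.41 in the PCBP1 and PCBP2 knockdowns. Pcbp2 fell by 0.53 (0.09, edgeR adjusted p = 1.74e-05) in the PCBP1 knockdown. Camera called 19 lists in each knockdown, and 4 and 2 of them held with an estimated correlation. Library totals moved the median of all genes by -1.43 and -1.42.

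Whether a knockdown effect differed between the days was tested by the interaction of condition and day. For PCBP1, 23 genes had a more positive and 47 a more negative effect at Day 2 (edgeR), among them Reps2, Mtrf1 and Trdc on one side and Slc7a5, Dusp1 and Slc2a1 on the other. With scrambled controls only, Slc7a5 (edgeR adjusted p = 0.085), Dusp1 (0.197) and Slc2a1 (0.135) were not called. Without single libraries 18 to 220 genes were called, against 70, and scaled to library totals the effect was more positive for 334 and more negative for 26. For PCBP2, edgeR called 0 genes, with 1583 at an unadjusted p under 0.05, and DESeq2 called 90. Values that did not pass for PCBP2 include -0.76 for the RNA helicase gene Ddx19a (edgeR adjusted p = 0.131), -0.95 for Slc43a2, -0.84 for Ninl, 1.19 for Atg9b, 1.53 for Rcor2 and 1.25 for Ahcy. Those of the erythroid transcription factors Zbtb7a, Zfpm1 and Klf1 were -0.87, -0.76 and -0.78 (edgeR adjusted p = 0.252 to 0.268).

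The authors' deposited tables of local splicing variations address which splicing choices each knockdown altered. They list pooled values per group without a replicate error or a depth. The change in points is the authors' own expected value, which need not equal the difference between the pooled shares. With a change of at least 20 points and a probability of at least 0.95, 69 variations in 58 genes changed in the Day 0 PCBP1 knockdown and 14 in 12 genes in the Day 0 PCBP2 knockdown. At Day 2 there were 168 in 135 genes and 62 in 59 genes. Of these, 3 and 5 at Day 0 and 1 and 0 at Day 2 were a choice between a junction and a retained intron alone.

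In the Day 0 PCBP1 knockdown, use of a junction of Dmtn (chromosome 14, 70618029 to 70618239) went from 84.9% to 24.6%, a change of -61.7 points. At Day 2 the same junction went from 69.2% to 20.3% (-50.4 points). By Salmon, the 2 Dmtn transcripts with this junction were set against 1 other, not against all counts of the gene. They made up 92.9 ± 0.757% of the counts compared in the Day 0 controls and 86.5 ± 0.992% in the PCBP1 knockdown, a smaller difference in the same direction. Other large changes at Day 0 were in the pseudouridine synthase gene Rpusd1 (65.7% to 18.9%), the transcription factor gene Tcf3 (12.1% to 57.1%), the calcium pump gene Atp2a2 (12% to 55.3%) and the tubulin acetyltransferase gene Atat1 (60.3% to 16%). At Day 2, Ocel1 (23.9% to 85.9%), Tsnaxip1 (61.3% to 2.2%), the anaphase-promoting complex gene Fzr1 (7.5% to 65.5%) and Gltscr1 (3.5% to 55%) changed most. Splicing of 7 genes changed on both days with PCBP1 knockdown (Carm1, Dmtn, Grk6, Ocel1, Pcyt2, Sbf1 and Sidt2), where 0.638 were expected from the genes listed in both tables (Fisher's exact test, one-sided, p = 2.55e-06).

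In the PCBP2 knockdown, a Runx1 junction that skips a coding exon of 192 nucleotides (chromosome 16, exon 92644154 to 92644345, junction 92613760 to 92668708) changed on both days. Runx1 codes for a transcription factor of definitive hematopoiesis. Use of the skipping junction went from 34.7% to 65.6% at Day 0 (31.3 points, probability 0.982) and from 41% to 72.6% at Day 2 (32.5 points, probability 0.993). In the PCBP1 knockdown the same junction was at 36.2% and 51.2%, with deposited changes of -1.62 and 6.65 points that did not pass. The deposited change is not the difference of the deposited shares, and at Day 0 the sign is opposite to that of the difference from the 34.7% of the controls. By Salmon, the 1 Runx1 transcript with this junction was set against 2 others, not against all counts of the gene. Its share was 34.7 ± 2.1% in the Day 2 controls, 31.8 ± 1.3% in the PCBP1 knockdown and 48.7 ± 2.8% in the PCBP2 knockdown. At Day 0 these shares were 35.3 ± 0.21%, 34.9 ± 0.45% and 38.3 ± 2.8%. A Btbd2 junction (chromosome 10, 80647861 to 80648560) went from 98.9% to 60.7% in the Day 0 PCBP2 knockdown, where Btbd2 expression also fell, and changed by -2.01 points in the PCBP1 knockdown. At Day 2, a junction of the ankyrin gene Ank1, which anchors the red cell membrane skeleton, went from 62.9% to 11% (chromosome 8, 23035245 to 23037167, an intron absent from the annotation), the aminopeptidase gene Metap1 from 17.6% to 73.4% and the WAVE complex gene Nckap1 from 97.9% to 44.2%.

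**Figure D5:**
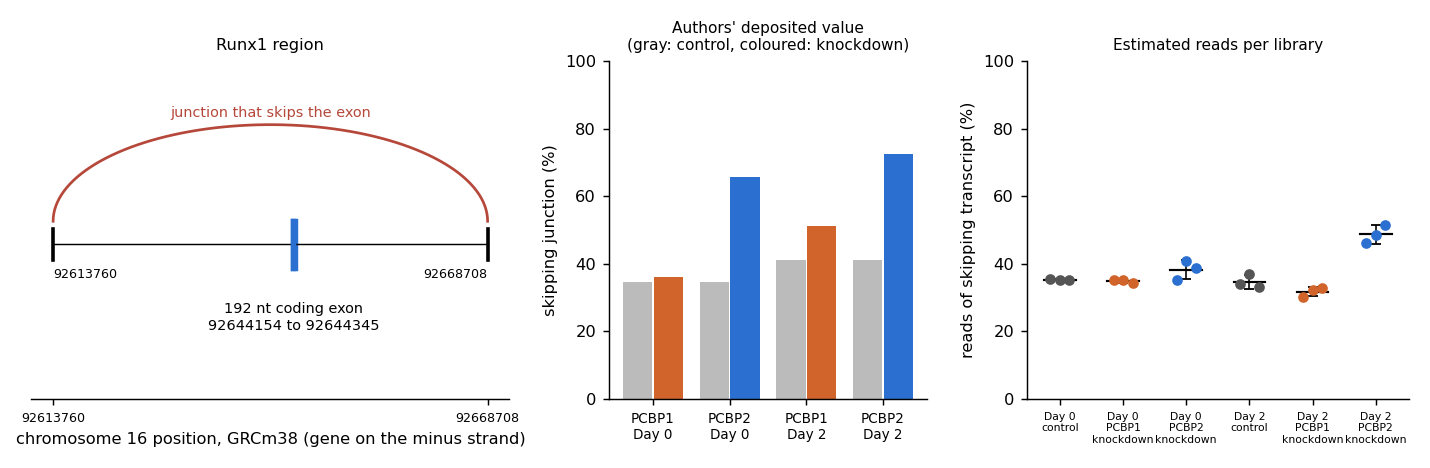
Map of the Runx1 junction and the exon it skips, its use in percent from the authors' deposited tables (pooled values), and the share by Salmon in each library of the 1 transcript with this junction, set against 2 other Runx1 transcripts, with the mean and SD of 3 libraries. The deposited value rose from 34.7% to 65.6% at Day 0 and from 41% to 72.6% at Day 2 with PCBP2 knockdown.

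Both knockdowns changed splicing of Clstn3, Ikbip and Mfge8 at Day 0 (3 genes, 0.0687 expected, Fisher's exact test, one-sided, p = 3.77e-05). A Clstn3 junction, set against a retained intron in a gene for a membrane adhesion protein, went from 51.2% to 96.3% with PCBP1 and to 93.7% with PCBP2 knockdown. By Salmon, set against 1 other transcript, the 2 Clstn3 transcripts with this junction made up 96.5 ± 3.1% in the Day 0 controls, 98.8 ± 2.2% with PCBP1 and 97.5 ± 3.1% with PCBP2 knockdown, differences within the spread between libraries. An Mfge8 exon of 111 nucleotides, in a gene for a phagocytosis bridging protein, had inclusion of 15.5% in the controls, 49.6% with PCBP1 and 49.2% with PCBP2 knockdown. At Day 2, Dleu2, Gltscr1, Naa16, Ptpn11, Sp3, Specc1 and Vkorc1l1 changed in both (7 genes, 1.01 expected, Fisher's exact test, one-sided, p = 6.02e-05). Both tables of a day share their controls, which raises such overlaps. At Day 2, 42 of 134 genes with changed splicing also fell in expression with PCBP1 knockdown, 31.3% against 13.1% of other listed genes (odds ratio 3.04, Fisher's exact test, two-sided, p = 5.04e-08; 1.75, 1.16 to 2.66, with abundance and GC content in the model), and 8 of 58 did with PCBP2 knockdown, 13.8% against 7.13% (p = 0.0669). At Day 0, 4 of 58 did with PCBP1 knockdown, 6.90% against 1.37% (Fisher's exact test, two-sided, p = 0.00883). The test of transcript shares called 159 and 80 genes at Day 0 and 333 and 324 at Day 2 for PCBP1 and PCBP2 knockdown, and most of its calls on simulated data were false.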

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

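The tests of the interaction of knockdown and day were planned, as were those of the C share of 3' untranslated regions, of abundance and GC content and of the number of listed variations, while the tests of GC bias, transcript length, progress along the day change and the luciferase control, the use of scrambled controls only, the 9-library fits and the counts over other splits of the libraries, were chosen after the results were seen.

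The effect of PCBP1 knockdown differed between Day 0 and Day 2 for 70 genes by edgeR (interaction, adjusted p from 9.68e-04 to 0.0458 among the genes named here). The effect was more positive at Day 2 for Trdc (log2 difference 2.48), Mtrf1 (1.78), Reps2 (1.70), Oxsm (1.18), Galk2 (1.16), Akr1b10 (1.12), the copper transporter gene Atp7a (1.10) and Eid1 (1.07). It was more negative for Urb2 (-1.17), Sh3bp2 (-1.07), Dusp1 (-1.06), Mnt (-1.03), Maff (-1.02), Fam76a (-0.96), Zbed4 (-0.92), Slc2a1 (-0.89), Fbxo7 (-0.66) and Slc7a5 (-0.59). With scrambled controls only, Fam76a, Maff, Fbxo7, Slc7a5, Atp7a, Akr1b10, Dusp1 and Slc2a1 were no longer called (adjusted p from 0.0589 to 0.197). Of 60 splits of the same libraries, 5 gave at least 70 genes, so chance is not excluded for this count. Without single libraries it ran from 18 to 220, and library totals gave 334 more positive and 26 more negative. The highest other split called 366 genes, and its cause was not identified. The splits regrouped the libraries of each day separately, so a split could keep the true knockdown groups of a day and hold their effect. They therefore do not show what would arise without any knockdown effect, and cannot decide this question.

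By camera the effect of PCBP1 knockdown also differed between the days for 12 lists. It was lower at Day 2 for the erythroid membrane (adjusted p = 2.17e-06) and the integrated stress response (2.17e-06), the erythroid splicing genes (0.00110), terminal maturation (0.00279), immediate-early genes (0.00472), erythroid transcription factors (0.0124) and heme synthesis (0.0388). It was higher for DNA replication (1.03e-05), oxidative phosphorylation (5.22e-05), mitosis (5.42e-04), ribosomal proteins (0.00110) and mitochondrially encoded transcripts (0.0421). All 12 had adjusted p between 0.468 and 0.844 with an estimated correlation. Scrambled controls only left 8 lists called and library totals 7, without the erythroid transcription factors (adjusted p = 0.120 and 0.232), heme synthesis (0.553 and 0.466), terminal maturation (0.0817 and 0.132) and mitochondrially encoded transcripts (0.772 and 0.0723), nor DNA replication with scrambled controls only (0.109) or the erythroid splicing genes with library totals (0.104). The 8 include the interferon response (0.0103), which is not among the 12. Of 60 splits drawn, 2 gave as many lists, the real one and another that also gave 12, a share under 0.05 for the count of 12 with the preset correlation. Since splits could hold the knockdown effect of a day, this share is not measured against groups without any effect.

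For PCBP2 knockdown camera found 9 lists whose effect differed between the days. It was lower at Day 2 for the erythroid transcription factors (adjusted p = 3.29e-10, adjusted p = 0.016 with an estimated correlation), the erythroid splicing genes (3.04e-07, and 0.016 with an estimated correlation), the erythroid membrane (7.94e-10, then 0.248), mitosis (2.67e-06, then 0.729), heme synthesis (8.38e-05, then 0.499), terminal maturation (1.79e-04, then 0.548) and DNA replication (0.00775, then 0.801). It was higher for p53 targets (1.43e-04, then 0.729) and macrophage genes (0.00884, then 0.548). The erythroid splicing genes include the target Pcbp2, whose own effect differed between the days by -0.48 (edgeR adjusted p = 0.408). With library totals, terminal maturation (0.0618), DNA replication (0.186) and macrophage genes (0.0628) were not called, nor were macrophage genes with scrambled controls only (0.0523). Of 60 splits, 23 gave at least 9 lists and the highest other gave 12, so chance is not excluded. These splits too could hold the knockdown effect of a day. By edgeR 0 genes passed, where 1583 had an unadjusted p under 0.05, DESeq2 called 90, and the highest other split called 20, all 60 of 60 splits giving at least 0.

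Pattern 1 is that erythroid lists (transcription factors, membrane, heme synthesis and terminal maturation) were lower at Day 2 in both knockdowns by camera with its preset correlation, where an estimated correlation left the transcription factors in the PCBP2 knockdown (adjusted p = 0.00423) and not the other 7 of 8 results (0.107 to 0.49). The luciferase control that stood apart at Day 2 is argued against as the cause of these camera results, since 8 of 8 list results still passed camera at the preset correlation without it, and so is GC bias, since 8 of 8 passed with the GC trend removed. Other splits of the Day 2 libraries gave up to 12 (PCBP1) and 11 lists (PCBP2) at that correlation, so passing camera is a weak criterion here. The 8 results share their controls, so they are not independent, and a deviation of all these controls stays open. A candidate explanation for PCBP1 is slower progress along differentiation: its Day 2 effect had a Spearman rho of -0.209 across genes with the day change of the PCBP2 knockdown, which shares no library with it (-0.265 to -0.123 without single libraries). Of the 6038 genes that rise at least 2-fold with that day change 58.1% were lower (median -0.0862), and of the 5891 that fall as much 65.0% were higher (median 0.131). These shares depend on how the libraries are scaled. For PCBP2 the same correlation was 0.0335 (-0.0303 to 0.144), which argues against general slowing as the cause, so a narrower effect on the erythroid genes stays open for it. Direct loss of binding of either protein to these transcripts was not tested.

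Pattern 2 is that 150 of the 156 genes called in the Day 0 PCBP1 knockdown fell. It is weaker in the 9 libraries of Day 0, where 248 rose and 863 fell, and weaker again with the GC trend removed there, where 130 rose and 203 fell. GC bias is argued against as the whole cause for 18 genes, which stayed called with the GC trend removed. For the others it cannot be told apart from an effect on GC-rich transcripts: their median went from -0.66 to -0.432 with the trend removed, below 0 but with a median adjusted p of 0.302. Across genes, transcript length (Spearman rho 0.0544) and the total C share of the 3' untranslated region beyond GC content (partial rho -0.0298) are argued against. The latter does not measure C-rich stretches or the 150 genes alone. A role of PCBP1 binding anywhere in these transcripts could remain beside the GC trend.

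Pattern 3 is that genes with changed splicing fell more often in the Day 2 PCBP1 knockdown. Abundance and GC content together are argued against as the whole cause, since the odds ratio stayed at 1.75 (1.16 to 2.66) with both in the model, against 3.04 without them. The number of listed variations is argued against as well (odds ratio 2.90, 2.00 to 4.22). A link between altered splicing and lower transcript levels, such as decay of misspliced transcripts, may account for part of it and was not tested.

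Over the 10 splits of 3 against 3 libraries, which are too few for a share under 0.05, the real split alone (1 of 10) gave as many genes in each comparison. The real and highest other counts were 156 and 1 (PCBP1, Day 0), 4 and 0 (PCBP2, Day 0), 45 and 1 (between knockdowns, Day 0), 2268 and 137 (PCBP1, Day 2), 818 and 19 (PCBP2, Day 2) and 2158 and 2 (between knockdowns, Day 2). Between the days they were 14490 and 0 in the controls, 14343 and 0 in the PCBP1 and 14523 and 0 in the PCBP2 knockdown. The lists separated real from other splits less: 4 splits gave as many at Day 0 for PCBP1 (6, highest other 8) and PCBP2 (8 and 9), 2 between knockdowns (7 and 8), 3 at Day 2 for PCBP1 (11 and 12) and PCBP2 (10 and 11) and 4 between knockdowns (8 and 11). Between the days, 4 splits did in the controls (19 and 19), 1 in the PCBP1 (19 and 18) and 2 in the PCBP2 knockdown (19 and 20). For transcript shares the counts were 159 and 85, 80 and 78, 333 and 254, and 324 and 234.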

How the results depend on the processing

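Leaving out single libraries, the other expression filters, DESeq2, limma-voom, library totals, offsets for effective length, the compared libraries alone, replicate blocks and the 2-fold minimum were planned, while scrambled controls only, the GC trend removed in each library and the 9 libraries of the day were chosen after seeing the data. Results are given in the order PCBP1 Day 0 (156 genes), PCBP2 Day 0 (4), between knockdowns Day 0 (45), PCBP1 Day 2 (2268), PCBP2 Day 2 (818), between knockdowns Day 2 (2158), and the interactions with day for PCBP1 (70) and PCBP2 (0). A 2-fold minimum left 24, 2, 17, 409, 98, 292 and 21 genes in the comparisons with calls, by its own construction. Of the filters, no filter beyond 1 count gave 479, 65 and 275 genes at Day 0 and 505 and 169 for the interactions. DESeq2 called 431, 13 and 161 genes at Day 0, 1558 for PCBP2 Day 2, and 598 and 90 for the interactions, and limma-voom called 335 for PCBP1 Day 0 and 116 between knockdowns at Day 0. Scaling to library totals called 4087 for PCBP1 Day 2 and 360 for its interaction, where the median of all genes moved by 0.23 (split 3459 higher and 628 lower, against 953 and 1315; interaction 334 and 26, against 23 and 47), and for PCBP2 Day 2 it moved by 0.20 (974 and 219, against 167 and 651). With the compared libraries alone, the counts were 1366 and 246 for PCBP1 and between knockdowns at Day 0, 543, 8 and 1045 at Day 2, and 21 for the PCBP1 interaction. The spread differed between days (common dispersion 0.00766 and 0.0300), and the 9 libraries of the day, with another spread, gene filter and number of residual degrees of freedom, gave 1111 and 312 at Day 0 and 932, 66 and 519 at Day 2. An effective length offset gave 67, 2 and 24 at Day 0. A replicate block gave 339 (construct as random) for PCBP1 Day 0 and 23 (hairpin number fixed) between knockdowns at Day 0, though the numbers do not pair the samples: constructs correlated between days by -0.00920 to 0.0418. Scrambled controls only gave 263, 9 and 101 at Day 0 and 1447 and 537 for PCBP1 and PCBP2 at Day 2. With the GC trend removed the counts were 20 and 24 for PCBP1 and between knockdowns at Day 0, 420 for PCBP2 Day 2 and 126 for the PCBP1 interaction. For the counts that moved under DESeq2, limma-voom, the filters, the offset, the block, the compared libraries, the 9 libraries of the day and the scrambled controls the cause was not tested.

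Leaving out single libraries gave 19 to 139, 2 to 5, 10 to 38, 1489 to 2660, 448 to 985 and 1052 to 3068 genes for the 6 knockdown comparisons in that order, and 18 to 220 and 0 to 3 for the interactions. The PCBP1 Day 0 count was 38 without SCR-1, 28 without SCR-2, and 19, 92 and 45 without hairpins 1, 3 and 4. PCBP2 Day 0 gave 2 genes without SCR-1, SCR-2, hairpin 1 or hairpin 3. Between knockdowns at Day 0 there were 10 genes without PCBP1 hairpin 1 or 4, and 13 and 22 without PCBP2 hairpins 1 and 4. PCBP1 Day 2 gave 1498 without LUC-1 and 1489 without hairpin 1, PCBP2 Day 2 gave 448 without hairpin 4, and between knockdowns 1052 without PCBP1 hairpin 1 and 1093 without PCBP2 hairpin 4. The PCBP1 interaction gave 18 without the Day 0 hairpin 1, 220 without the Day 2 hairpin 3 and 193 without the Day 2 SCR-1, and PCBP2 gave 3 without the Day 2 LUC-1. The fall of Pcbp1 at Day 0 (-2.59) was no longer called with the compared libraries alone (-2.58), scrambled controls only (-2.54) or the GC trend removed (-2.34), and single libraries left out gave -3.35 to -2.22. The knockdown of Pcbp1 at Day 2 and of Pcbp2 on both days kept its call in all alternatives tried.

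Of the other values, 9 reversed. Scaled to library totals, the day change in the controls became -0.17 for Vwf, -0.36 for Pf4, -0.33 for Pecam1 and -1.19 for Pcbp1, in the PCBP1 knockdown -0.34 for Rpl28 and -1.22 for Pcbp1, and in the PCBP2 knockdown -0.26 for Pf4 and -1.16 for Pcbp1, where that scaling moved the median of all genes by -1.63, -1.43 and -1.42. Hnrnpk had a day change of 0.076 in the controls with genes of at least 1 CPM in 3 libraries, against -0.18, and the cause was not tested. Of the values that are not main results, 26240 kept direction and side of the threshold, 575 newly passed, 1156 no longer passed, and of the main results 274 were the same, 115 moved and 8 no longer passed. With an estimated correlation in place of camera's preset one, the lists called were 0 (PCBP1) and 1 (PCBP2) at Day 0, 1 between knockdowns, 0 and 3 at Day 2, 0 between knockdowns, 2, 4 and 2 between the days, and 0 and 2 for the interactions. Fry called 1, 1 and 1 at Day 0, 10 for PCBP1, 6 for PCBP2 and 7 between knockdowns at Day 2. It called 29, 28 and 27 between days in the controls, PCBP1 and PCBP2 knockdowns, and 0 and 2 for the interactions. The deposited splicing calls fell from 69, 14, 168 and 62 to 27, 7, 96 and 26 variations at a probability of 0.99, a stricter limit. Transcript share calls with transcripts of at least 10% of their gene were 8, 3, 73 and 77, against 159, 80, 333 and 324, and by the F test 48 (PCBP2 Day 0), 660 and 565 (Day 2), and the cause was not tested. The correlation between the knockdown effects ran from 0.401 to 0.618 at Day 0 and from 0.438 to 0.655 at Day 2 without single libraries, and at an unadjusted p 234 and 1338 genes were shared, where simulated counts without a knockdown effect and with the same controls shared 62.9 and 404. The simulated counts held no GC trend and no library that stands apart. No alternative varied the depth (27033440 to 54096339 estimated reads). Simulated changes of 0.5 log2 units at Day 0 were called in 7 of 67 (PCBP1) and 13 of 67 genes (PCBP2) with the pooled spread, and in 39 of 61 and 37 of 65 in the 9-library fits. At Day 2 they were called in 4 of 63 and 14 of 65, and in 0 of 55 and 5 of 57, so most changes of that size were missed by either fit at Day 2 and by the pooled fit at Day 0.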

Other observations

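The comparisons with scrambled controls only, the fits of the 9 libraries of a day and the estimates of the GC trend used here were chosen after the results were seen.

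Besides Pcbp2, the 3 genes that fell at Day 0 in the PCBP2 knockdown, Btbd2, Cdc25b and Depdc1b, fell again at Day 2. Cdc25b also fell in the PCBP1 knockdown at Day 2 (-0.71 by edgeR). Btbd2 also fell in the PCBP1 knockdown at Day 0, while in the deposited tables use of 1 of its junctions changed by -37.6 points with PCBP2 and by -2.01 with PCBP1 knockdown. Depdc1b differed between the knockdowns at Day 0 (-0.72 by edgeR). The mitosis list tested higher in the PCBP2 knockdown at Day 0 (median 0.07, camera adjusted p = 0.0251, adjusted p = 0.987 with an estimated correlation). Got1, Galk1 and Fdxr fell in the PCBP1 knockdown at Day 0 and differed between the knockdowns (1.34, 1.13 and 1.11 by edgeR). Blvrb fell in the PCBP1 knockdown on both days (-1.06 and -1.11) and in the PCBP2 knockdown at Day 2 (-0.87).

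At Day 2, 14 of 24 integrated stress response genes fell in the PCBP1 knockdown and 3 of 24 in the PCBP2 knockdown, and 13 of 24 were higher in the PCBP2 than in the PCBP1 knockdown. Of the DNA replication genes 17 of 28, and of the mitosis genes 14 of 26, were lower in the PCBP2 than in the PCBP1 knockdown. These counts rest on the pooled spread, with which 33.8% (PCBP1) and 27.4% (PCBP2) of simulated Day 2 calls against control were false, and the differences between the knockdowns in these lists did not pass with an estimated correlation (camera adjusted p = 0.366, 0.478 and 0.366). Which knockdown departs from control in the DNA replication genes depended on the controls used. With scrambled controls only, DNA replication tested lower in the PCBP2 knockdown (camera adjusted p = 4.72e-07, up to 0.590 over 5 alternatives) and was not called in the PCBP1 knockdown (0.0644, down to 1.3e-05 over 5 alternatives).

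Runx1 was the 1 gene whose splicing passed on both days in the deposited PCBP2 tables (0.0451 expected, Fisher's exact test, one-sided, p = 0.0443). The skipping transcript also differed in its Salmon share, taken against 2 other Runx1 transcripts, at Day 2 (48.7 ± 2.8% against 34.7 ± 2.1%) and less at Day 0 (38.3 ± 2.8% against 35.3 ± 0.21%, where the deposited change was 31.3 points), and Runx1 expression fell at Day 2 (-0.49, edgeR adjusted p = 0.0347) with the pooled spread only. Whether the skipped exon relates to the lower erythroid lists was not tested.

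Trdc, Il7r and Aldh1a1, genes better known from lymphoid or stem cells than from erythroblasts, rose in the Day 2 PCBP1 knockdown and were lower in the PCBP2 than in the PCBP1 knockdown (-1.67, -1.99 and -1.98 by edgeR). The list of lymphoid markers as a whole was not called, with 1 of 5 members higher. C1qa, a macrophage gene, was at 0.266 ± 0.27 CPM in the Day 2 controls and is listed at 0 in the Day 2 PCBP1 knockdown libraries. The Day 0 library of PCBP2 hairpin 3 had the most reads of the 18 (54096339) and a GC trend of -0.284, against 0.158 and 0.143 for hairpins 1 and 4.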
